A study of Homo sapiens with 8 samples.

How the data were processed

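RNA from HSC-4 and OSC-19, cell lines of human squamous carcinoma of the mouth, was measured on 8 one-colour Agilent arrays, 4 for each line. Per the labels' protocols, the cells were grown in RPMI1640 and DMEM with serum, without a statement of which line received which medium. Total RNA was labelled with Cy3. Group and replicate number were taken from the sample descriptions, and no array was left without a group. The labels do not say that the 4 arrays of a line came from separate cultures, so every p-value measures only the spread between these arrays, which may be technical.

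The deposited files of each array hold spot intensity, read with Agilent Feature Extraction 10.10.1.1 per the submitters' processing notes. Per the file headers, the processed intensity was background-subtracted and detrended across the surface of the array, with a floor on low signals and no normalization between arrays. The spot flags, coded 0 or 1 per the file headers, mark spots that are saturated, outlying or well above background. The file headers also give the design of the array on build hg19. The authors additionally deposited 1 table of log2 values for the series. Its software and normalization are not given in the sources used here.

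The scale, centring and direction of that table were worked out by setting each column against the scanner values. Over 34122 probes, each column followed the log2 processed signal of 1 array, scaled to its 75th percentile and centred on each probe's median over the arrays. The largest absolute median of a probe over the 8 columns was 1e-06. The array that each of the 8 columns followed was the array filed under the other cell line with the same replicate number, with r from 0.9999 to 1.0. With the scanner file of its own name, r lay between -0.614 and -0.552. Column medians of the HSC-4 columns were -0.04, 0.03, 0.08 and 0.11 for replicates 1 to 4, and those of the OSC-19 columns were -0.13, -0.13, -0.08 and 0.09. None of the scanner files names a cell line in its text, so the correct assignment stays unknown. All values below follow the filing of the scanner files, and the deposited table gives the opposite direction for every difference between the lines.

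Each array held 43118 spots of 34127 probes once control spots were left out. Spots marked as non-uniform or as population outliers, 265 to 374 per array, were removed, and no spot was saturated. Spots of the same probe were averaged. The main values were log2 of the processed signal minus the 75th percentile of that array. A probe was kept when it was well above background on all 4 arrays of at least 1 line, which left 23427 probes. Between 66.9% and 74.1% of probes were well above background on an array, and the number of arrays limits the precision of each value.

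Probes were named by matching the accession in the scanner files, without version, to a RefSeq gene table of assembly GRCh38.p14. A symbol was found for 25502 probes (74.7%), covering 19539 symbols, and 8625 probes stayed unnamed. The assembly differs from the build of the array, so the table was used only for names and for the order of genes. Each gene was represented by its brightest kept probe, giving 14712 named genes and 4268 unnamed transcripts, which were adjusted together. Among 3569 genes with more than 1 kept probe, probes disagreed past the threshold in opposite directions for 81 genes, and for 17 by at least 2-fold each way.

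Differences were taken as OSC-19 minus HSC-4 and fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3, without covariates. P-values covered both directions, with Benjamini-Hochberg adjustment and a threshold of 0.05. A gene with no probe, kept or not, well above background on any array of a line had only a bound there, and a gene with a further probe above background in that line was not ranked among the bounds. Its fold is then given as at least N-fold, from the mean of the bright line against the mean, over the arrays of the dim line, of the higher of the lowest signal well above background and the probe's own signal. A total of 37 gene lists were written from textbook knowledge before the data were examined. Lists with at least 5 tested members, 36 in all, were tested with camera of limma at a preset correlation of 0.01 between genes. Camera with an estimated correlation and fry were run beside it. Fry asks whether the members of a list move one way on balance, and its mixed form whether they change either way, without comparing them with other genes. Each list had the same median, to 3 decimals, with bounded genes set to their bound.

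Genes named in the text followed a rule also fixed before the data were examined. It took the 8 largest differences in each direction among genes above background on all 8 arrays, the 6 largest bounds in each direction, up to 3 members with the largest differences in each list, and a set of fixed single genes. The fixed genes used here, given whatever their result, were CDH1, VIM, TP63, EGFR, CDKN2A, CCND1, SNAI2, CD44, MMP9, PDPN, WNT5A, WNT5B and KRT19. Some genes that the rule takes are not reported here. Any other gene named was chosen after its values were seen.

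Both slides held 2 arrays of each line, and all arrays of a slide shared 1 scan, so slide and scan could not be separated. Replicates 1 and 2 of both lines lay on slide 1 and replicates 3 and 4 on slide 2. Deviations from the line means correlated between the lines at r from 0.561 to 0.631 for the same replicate number. The same number therefore met the criterion for pairs, although different numbers on the same slide gave r from 0.542 to 0.623, and different slides gave -0.637 to -0.527. The pairing thus rests on the slide. Slide and replicate number were each fitted as a block, and each slide was also tested alone.

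Alternatives fixed in advance were quantile or median scaling, the deposited table, other filters on dim probes, other handling of probes of a gene, the slide and replicate blocks, a trended robust variance, array weights, treat, other set tests and leaving out each array. The normexp correction was planned on mean spot signals, which the scanner files do not give, and was run on median spot and background signals with an offset of 50. That change, the deposited table with its columns exchanged between the lines, and the averaging of both arrays of a line on a slide were added after seeing the data. The pipeline was tested on simulated data with the spread of these arrays. Of 50 genes changed at each size, it recovered 2% at a log2 difference of 0.5, 62% at 1, 96% at 2 and 100% at 4, and it called 1 of 18780 unchanged features. Only 200 genes were changed in the simulation, whereas 57% of named genes passed in the data. The adjustment is stricter where few genes differ, so these shares do not give the recovery of small differences in the data. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.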

Results

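Gene expression was measured in 2 cell lines of human oral squamous cell carcinoma, HSC-4 and OSC-19, with 4 one-colour arrays per line. Levels are log2 signals relative to the 75th percentile of the array, so a level of 0 is that of a bright probe. The single comparison that the design implies is between the lines, and the labels give no treatment. As the labels do not say which line grew in RPMI1640 and which in DMEM, medium may coincide with line and cannot be separated from it. The deposited value table assigns each array to the other line than the scanner files do, as the plot of table columns against scanner files shows. HSC-4 arrays and OSC-19 arrays below are those filed as such among the scanner files, and every signed difference, given as OSC-19 minus HSC-4, has the opposite sign in the deposited table.

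**Figure D1:**
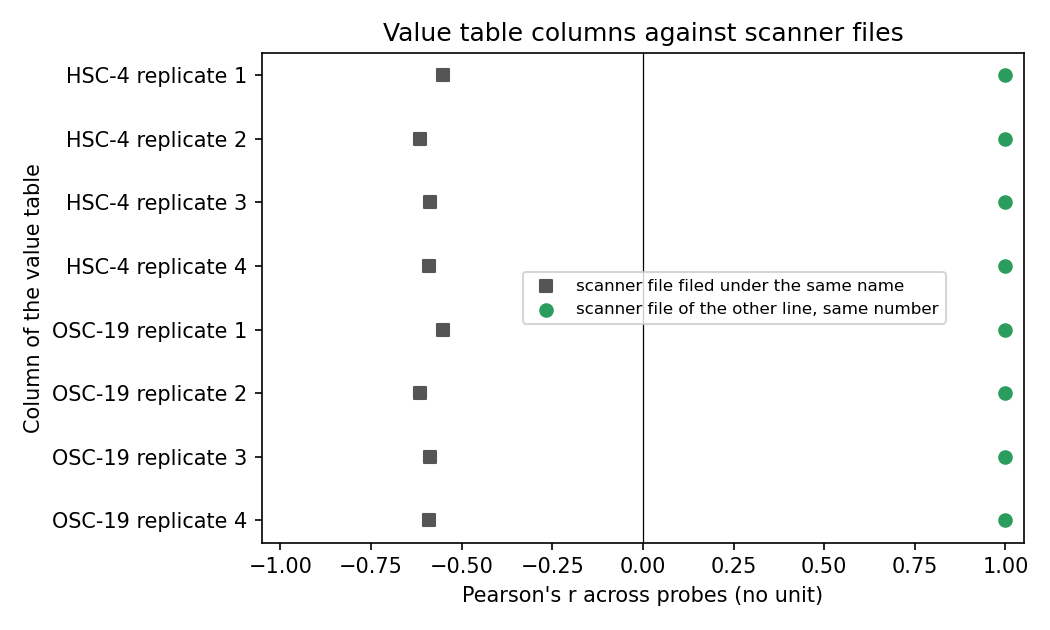
Pearson's r across probes (horizontal axis, no unit) between each column of the deposited value table (vertical axis) and the scanner file of the same name (squares) or that of the other line with the same replicate number (circles). All 8 columns lie at 0.9999 or above with the file of the other line, and between -0.614 and -0.552 with the file of the same name.

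The lines differed widely. Of 14712 named genes, 8388 (57%) passed the threshold in limma, 4376 higher and 4012 lower on OSC-19 arrays, with a median difference over all named genes of 0.01. At least 2-fold differences were found for 2302 higher and 1876 lower genes, and at least 16-fold differences for 326 and 172. A further view of presence gave 363 genes above background on OSC-19 arrays only and 166 on HSC-4 arrays only. The largest differences included those of KRT6A, GSTM3 and MMP1, higher on OSC-19 arrays, and of KRT19 and IGFBP3, higher on HSC-4 arrays.

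Arrays of the same line on the same slide correlated at 0.9960 to 0.9978, those of the same line on different slides at 0.9826 to 0.9864, and those of different lines at 0.8720 to 0.8960. In the plot of principal components, the first separated the lines and held 85.7% of the variance, and the second separated the slides and held 10.2%. The median SD of a gene was 0.23 within HSC-4 and 0.22 within OSC-19 (n = 4 each), against a median SE of the difference of 0.17. With slide as a block, 5757 genes were higher and 5418 lower. Within slide 1 alone these counts were 5523 and 5021, and within slide 2 alone 5208 and 4920. With normexp on median signals, 2814 genes were higher and 2402 lower, and with both arrays of a line on a slide averaged, 2152 and 1795.

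**Figure D2:**
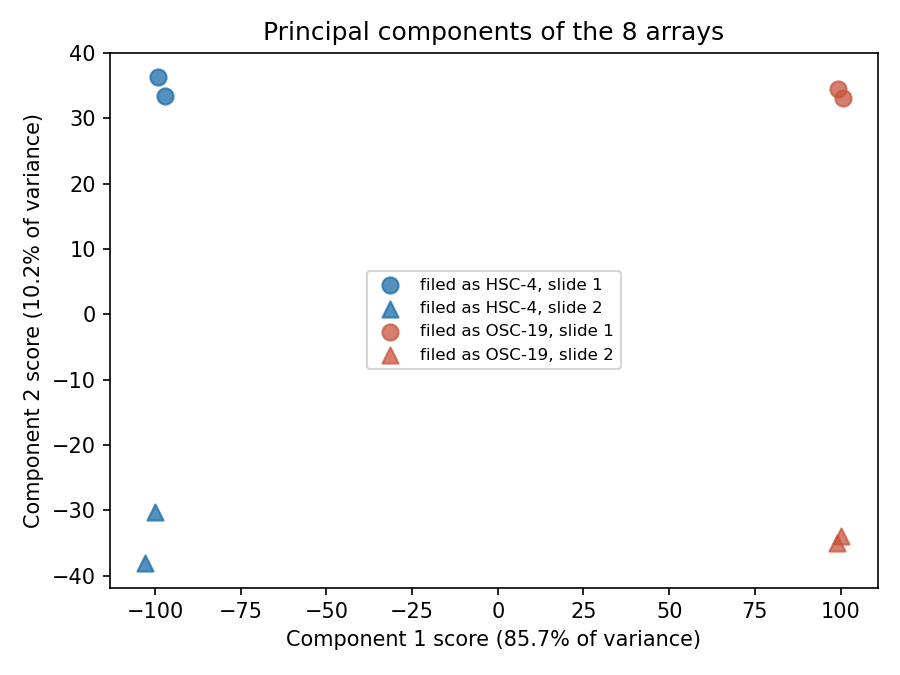
Scores of the 8 arrays on the first (horizontal axis) and second (vertical axis) principal components, in units of the component score, with colour for the line as filed and shape for the slide. The first component, with 85.7% of the variance, parts the lines, and the second, with 10.2%, parts slide 1 from slide 2 in both lines.

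Among genes above background on all 8 arrays, the largest differences in favour of OSC-19 were those of KRT6A, a keratin of stressed and hyperproliferative epithelium, and GSTM3, a glutathione transferase. KRT6A measured 5.39 ± 0.62 on OSC-19 arrays against -4.28 ± 0.22 on HSC-4 arrays (SD, n = 4), a difference of 9.66 (SE 0.29, adjusted p = 2.32e-08). GSTM3 differed by 9.58 (SE 0.09, adjusted p = 1.16e-10). The interstitial collagenase MMP1 was 553-fold higher, the mitochondrial creatine kinase CKMT1A 526-fold, the phosphatase DUSP23 354-fold and the neutrophil chemokine CXCL1 305-fold. The fast skeletal muscle troponin T gene TNNT3 was 203-fold higher, and the interferon-stimulated gene IFI44L was 120-fold higher, with a log2 difference of 6.91 (SE 0.53) that was 6.04 on slide 1 and 7.78 on slide 2. Probes of KRT6A, GSTM3 and CKMT1A may also bind transcripts of closely related copies. On HSC-4 arrays GSTM3 and CKMT1A measured -5.47 and -5.33, close to background. At a like level of -5.51, HES5 was above background on only 3 of the 4 HSC-4 arrays. The sizes of such differences are thus less certain than their SE implies.

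In favour of HSC-4, the largest differences were those of KRT19, a keratin of simple epithelia, and its processed pseudogene KRT19P2, whose probe cannot be separated from the parent gene. KRT19 measured 8.42 ± 0.24 on HSC-4 arrays and -1.45 ± 0.07 on OSC-19 arrays (SD, n = 4), a difference of -9.88 (SE 0.13, adjusted p = 9.59e-10), and KRT19P2 differed by -10.23 (SE 0.14). KRT19P2 measured -5.41 on OSC-19 arrays, close to background, so the size of its difference is less certain than its SE implies. The insulin-like growth factor binding protein IGFBP3 differed by -8.21, the haematopoietic adaptor HCLS1 by -7.76, the epidermal serine protease KLK5 by -7.74 and the GABA receptor subunit GABRP by -7.73. The peptidylarginine deiminase PADI3, which acts on hair follicle and epidermal proteins, differed by -7.68, and the cancer-testis antigen MAGEB2 by -7.63. Each of these 16 differences passed the threshold in limma on each slide alone. The genes were picked for their size on these same arrays, so this is no independent check.

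**Figure D3:**
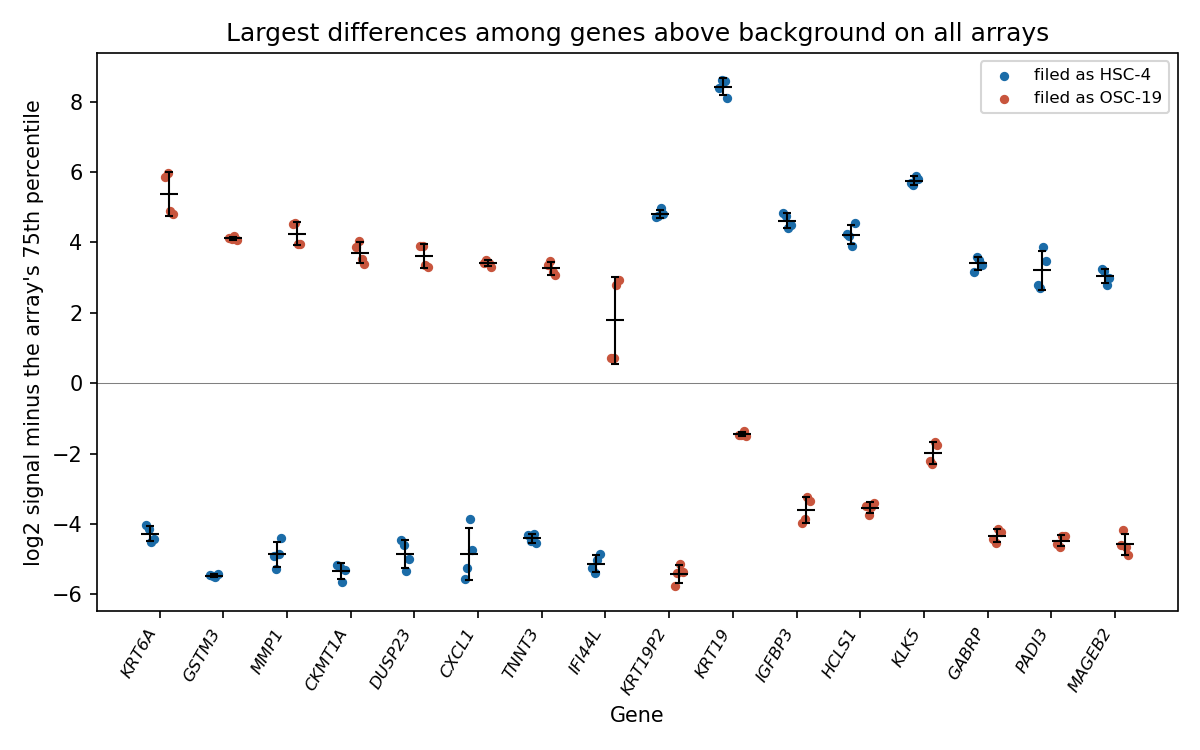
Log2 signal relative to the 75th percentile of the array (vertical axis) for the 8 genes with the largest positive and the 8 with the largest negative difference among genes above background on all 8 arrays (horizontal axis). Points are single arrays, coloured by the line as filed, and bars give the mean and SD (n = 4), with no overlap between the lines in any of the 16 genes.

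Several genes were above background in a single line, so that only a bound of the fold can be given. CYB5A, the microsomal cytochrome b5, was at least 584-fold higher on OSC-19 arrays, followed by the calcium-binding alarmin S100A8 at 372-fold, the formin FHOD3 at 185-fold and the serpin SERPINB3 at 155-fold. The neuronal calcium sensor VSNL1 and SLFN11, a helicase-like factor linked to sensitivity to DNA damage, followed at 143-fold and 140-fold. On HSC-4 arrays, the peroxidasin PXDN, which crosslinks collagen of basement membranes, was at least 1250-fold higher. The paternally expressed neighbours PEG10 and SGCE were at least 394-fold and 307-fold higher. CUZD1, IGFBP1 and the guanine deaminase GDA followed at 220-fold, 169-fold and 114-fold. All of these genes passed the threshold in limma.

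Of the 36 tested lists, 9 passed the threshold in camera at the preset correlation, 4 higher and 5 lower on OSC-19 arrays. With an estimated correlation none passed, the smallest adjusted p being 0.227, and by fry 26 lists passed in 1 direction. Without adjustment, 3 of the 36 had p under 0.05 with an estimated correlation, namely cholesterol synthesis (0.00916), inflammatory cytokines (0.0126) and YAP/TAZ targets (0.0263). In camera with an estimated correlation and slide as a block, each of these 3 had adjusted p = 0.737. Across the 35 ways to split the 8 arrays 4 against 4, 8 gave 9 or more lists, the real split included.

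**Figure D4:**
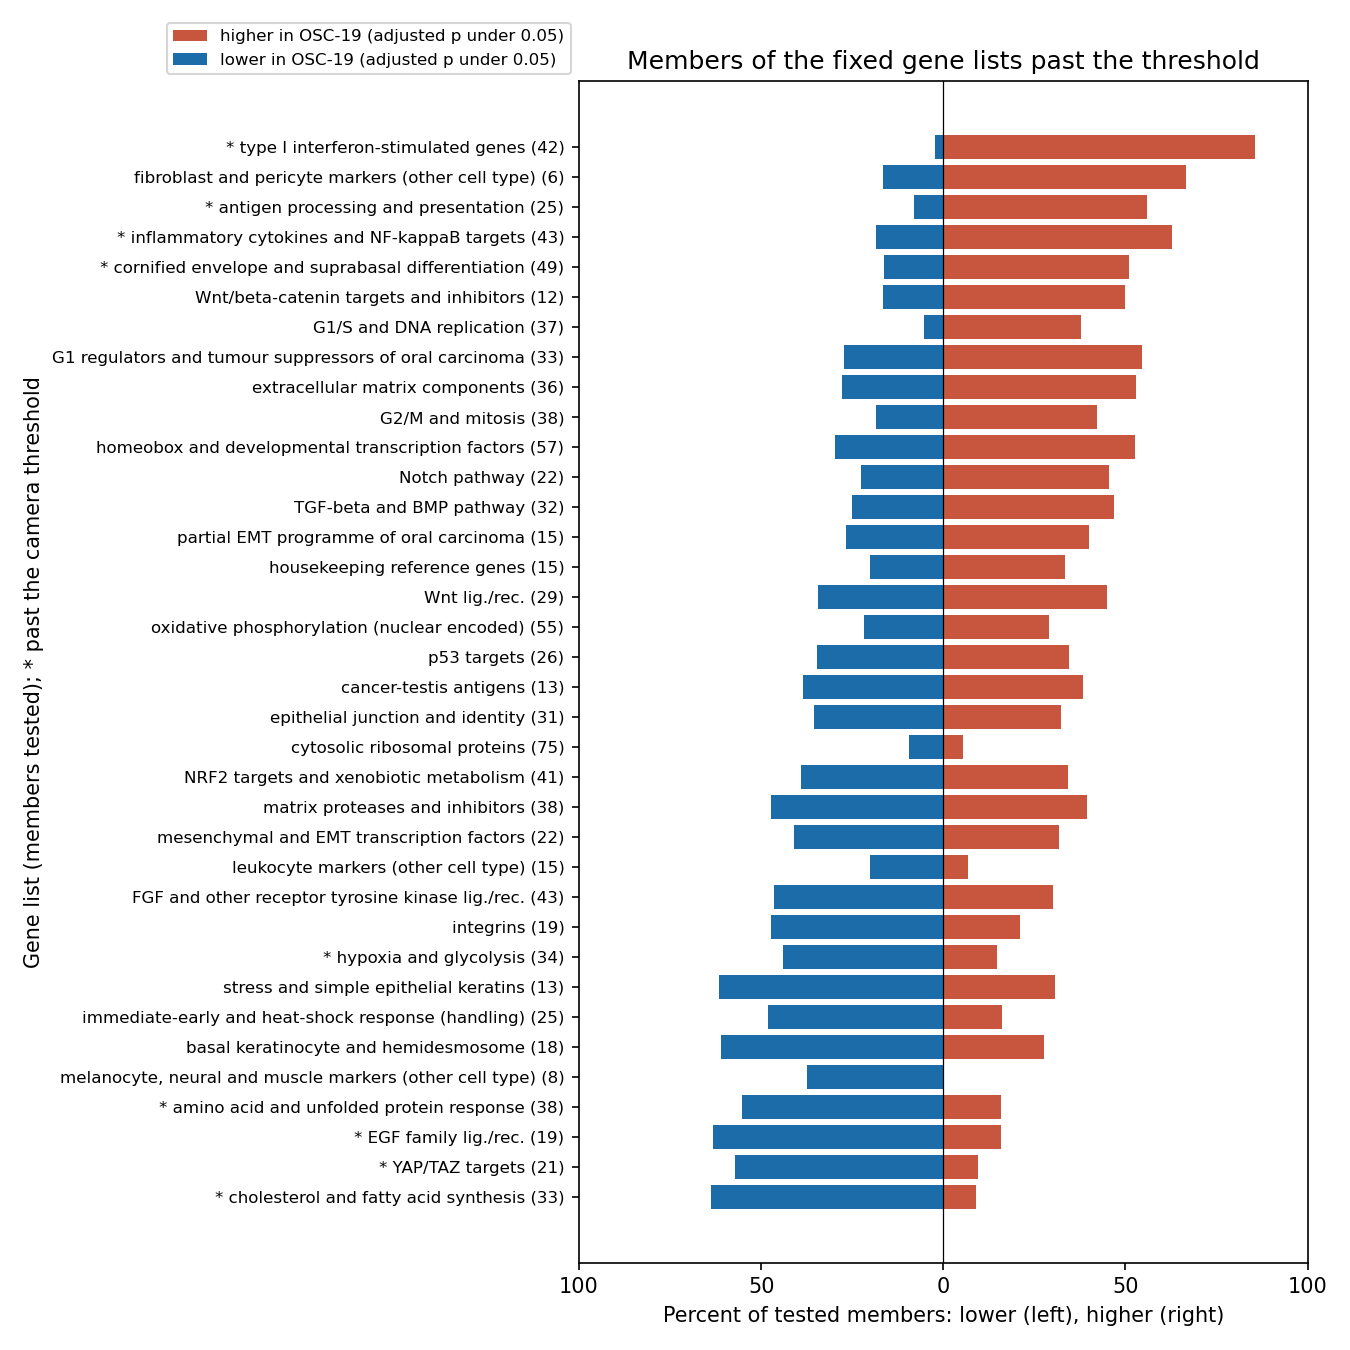
Percent of the tested members of each fixed gene list that passed the threshold in limma, higher on OSC-19 arrays to the right and lower to the left (horizontal axis), with the number of members tested in brackets. An asterisk marks the 9 lists that passed in camera at the preset correlation, led by the type I interferon-stimulated genes.

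Type I interferon-stimulated genes, the antiviral programme that follows signalling by interferon alpha and beta, were higher on OSC-19 arrays in 36 of 42 members, lower in 1 and not passing in 5. Adjusted over the list alone, 38 were higher and 1 lower. The median difference was 1.75, with a camera adjusted p of 5.34e-08, and adjusted p = 0.655 with an estimated correlation. It was 1.21 on slide 1 and 2.16 on slide 2. IFI44 rose by 5.03 (SE 0.22) on the log2 scale and EPSTI1 was at least 30.1-fold higher. Genes of antigen processing and presentation, which are partly under interferon control, were higher in 14 of 25 members and lower in 2, with 15 and 2 adjusted over the list alone. Their camera adjusted p was 0.0132, and adjusted p = 0.655 with an estimated correlation. The immunoproteasome subunit PSMB9 was 8.12-fold higher, the peptide-trimming aminopeptidase ERAP2 7.48-fold and B2M, the light chain of class I molecules, 3.44-fold. Probes of the HLA genes are open to sequence differences between lines.

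Inflammatory cytokines and NF-kappaB targets were higher in 27 of 43 members and lower in 8, and the same counts were obtained adjusted over the list alone. In camera the adjusted p was 0.00456, and adjusted p = 0.227 with an estimated correlation. Besides CXCL1, the monocyte chemokine CCL2 was at least 98.2-fold higher on OSC-19 arrays. LCN2, a siderophore-binding protein of inflamed epithelium, went the other way, and was above background on only 2 of the 4 OSC-19 arrays.

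Cornified envelope and suprabasal genes, expressed as keratinocytes mature, were higher on OSC-19 arrays in 25 of 49 members and lower in 8, with 25 and 9 adjusted over the list alone. The camera adjusted p was 0.0132, and adjusted p = 0.655 with an estimated correlation. This call was lost within slide 2, at 0.0942, and with only probes above background on all 8 arrays, at 0.178. SERPINB3 and S100A8 led the list and KLK5 went the other way. Basal keratinocyte genes were higher in 5 and lower in 11 of 18 members, with 5 and 12 adjusted over the list alone (camera adjusted p = 0.246). The basal keratins KRT5 and KRT15 were among the higher ones, 11.4-fold and 6.06-fold. TP63, the transcription factor of stratified epithelium, was 1.99-fold higher (adjusted p = 0.000218). Stress and simple epithelial keratins were higher in 4 and lower in 8 of 13 members, with the same counts adjusted over the list alone (camera adjusted p = 0.264). With only probes above background on all 8 arrays this list passed, lower on OSC-19 arrays, at 0.0117, but that filter drops higher members such as KRT6C. In the main setting it had adjusted p = 0.655 with an estimated correlation. KRT6C, a close copy of KRT6A, was also higher, and was above background on only 1 of the 4 HSC-4 arrays.

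EGF family ligands, receptors and feedback targets were lower on OSC-19 arrays in 12 of 19 members and higher in 3, also when adjusted over the list alone. The camera adjusted p was 0.0132, and adjusted p = 0.587 with an estimated correlation. The ligand EPGN fell by 3.97 (SE 0.32) and PHLDA1 fell by 3.60 (SE 0.27), whereas the ligand NRG4 was at least 16.6-fold higher. EGFR itself fell by 0.91 (SE 0.10, adjusted p = 6.16e-05). With the mean of its probes in place of the brightest, the EGFR difference was -0.39 and did not pass (adjusted p = 0.0594). YAP/TAZ targets were lower in 12 of 21 members and higher in 2, also adjusted over the list alone. For the list, camera gave an adjusted p of 0.00615, and adjusted p = 0.315 with an estimated correlation. IGFBP3 led them, followed by DLC1, often lost in carcinomas, at least 16.5-fold lower, and the ecto-nucleotidase NT5E, 5.41-fold lower. With normexp on median signals, DLC1 differed by -1.64, less than that bound, and did not pass (adjusted p = 0.0873).

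Cholesterol and fatty acid synthesis was lower on OSC-19 arrays in 21 of 33 members and higher in 3, with 22 and 3 adjusted over the list alone. The camera adjusted p was 0.00179, and adjusted p = 0.227 with an estimated correlation. The sterol oxidase MSMO1 fell by 4.68 (SE 0.23), the sterol carrier STARD4 by 2.98 and the lanosterol synthase LSS by 2.08. Hypoxia and glycolysis genes were lower in 15 of 34 members and higher in 5, with 16 and 5 adjusted over the list alone. Their camera adjusted p was 0.0132, and adjusted p = 0.655 with an estimated correlation. Within slide 1 it was 0.0981. The glucose transporter SLC2A3 was at least 37.5-fold lower and the oxygen sensor EGLN3 14.4-fold lower, whereas CA9, a carbonic anhydrase induced by hypoxia, was at least 14.3-fold higher.

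Genes of the amino acid response, serine synthesis and the unfolded protein response were lower in 21 of 38 members and higher in 6, also adjusted over the list alone. By camera the adjusted p was 0.0131, and adjusted p = 0.655 with an estimated correlation. The call was lost within slide 1, at 0.0981, and with quantile normalization, at 0.052. VLDLR, ATF3 and the glutathione-degrading enzyme CHAC1 fell by 3.89, 2.94 and 2.50. Immediate-early and heat-shock genes, which respond to the handling of cells, were lower in 12 of 25 members and higher in 4, with the same counts adjusted over the list alone (camera adjusted p = 0.137). Their leading member DUSP1 fell by 3.23 (SE 0.17), and ATF3 belongs to both lists.

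Lists of adhesion and invasion had members in both directions and did not pass in camera. By fry the junction list passed as lower (adjusted p = 0.0377) and the partial EMT list as higher (3.64e-06), whereas the mesenchymal list did not pass (0.662). Junction genes were higher in 10 and lower in 11 of 31 members (camera adjusted p = 0.758), with 10 and 12 adjusted over the list alone. Mesenchymal genes were higher in 7 and lower in 9 of 22 (0.862), with the same counts adjusted over the list alone. The partial EMT list was higher in 6 and lower in 4 of 15 (0.693), with 7 and 5 adjusted over the list alone. E-cadherin, CDH1, was 1.74-fold higher and vimentin, VIM, 2.42-fold higher on OSC-19 arrays. Averaging both arrays of a line on a slide left the differences at 0.80 and 1.27, and neither then passed (adjusted p = 0.0769 and 0.0515). Fibronectin, FN1, fell by 5.39 (SE 0.65) and the collagen-crosslinking LOX by 4.40 (SE 0.29), each above background on 3 of the 4 OSC-19 arrays, whereas smooth muscle actin, ACTA2, was 30.7-fold higher. SNAI2, a repressor of CDH1, fell by 0.44 (adjusted p = 0.00822), and did not pass with normexp (-0.25, adjusted p = 0.358) or with the arrays averaged (-0.44, adjusted p = 0.224). The podoplanin gene PDPN fell by 1.25 and the hyaluronan receptor CD44 by 2.13 (SE 0.17).

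Matrix proteases and inhibitors were higher in 15 and lower in 18 of 38 members, also adjusted over the list alone (camera adjusted p = 0.839). Besides MMP1, the elastase MMP12 and the collagenase MMP13 were at least 40.5-fold and 35.3-fold higher on OSC-19 arrays, while MMP9 differed by 0.16 (adjusted p = 0.288). Integrins were higher in 4 and lower in 9 of 19 (0.267), with 5 and 9 adjusted over the list alone. Matrix components were higher in 19 and lower in 10 of 36 (0.371), with 19 and 11.

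The Wnt, TGF-beta, Notch and FGF lists did not pass in camera. By fry, which does not compare a list with other genes, each passed, with adjusted p from 2.77e-06 to 0.00827. The direction by fry was lower on OSC-19 arrays for the FGF list and higher for the others. Wnt ligands and receptors were higher in 13 and lower in 10 of 29 members (camera adjusted p = 0.839), with 13 and 11 adjusted over the list alone. WNT5B was 27.9-fold lower, being above background on 3 of the 4 OSC-19 arrays, and WNT11 was at least 7.05-fold higher. WNT5A differed by -0.53 (adjusted p = 0.152), with -1.30 on slide 1 (adjusted p = 0.00022) and 0.25 on slide 2 (adjusted p = 0.0635). Wnt targets and inhibitors were higher in 6 and lower in 2 of 12 (0.371), also adjusted over the list alone. The TGF-beta and BMP list was higher in 15 and lower in 8 of 32 (0.458), with 16 and 9 adjusted over the list alone. The Notch list was higher in 10 and lower in 5 of 22 (0.228), with 11 and 5, and in it the receptor NOTCH3 was 8.44-fold higher and the effector HES5 was also higher, being above background on 3 of the 4 HSC-4 arrays. FGF and other tyrosine kinase genes were higher in 13 and lower in 20 of 43 (0.228), with 14 and 21.

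Replication genes of the G1/S phase were higher on OSC-19 arrays in 14 of 37 members and lower in 2, with 12 and 2 adjusted over the list alone. The camera adjusted p was 0.137, against 0.0378 with slide as a block, 0.0415 with the replicate block, 4.32e-05 within slide 2 and 0.363 within slide 1. With an estimated correlation it was 0.943, and 0.908 with slide as a block. Leaving out HSC-4 replicate 1 or 2 gave 0.0164 and 0.0257. The transcription factor E2F2, which drives entry into S phase, was 4.31-fold higher, and its difference of 2.11 was unchanged, with adjusted p = 0.0898, once both arrays of a line on a slide were averaged. G2/M genes were higher in 16 and lower in 7 of 38 (0.449), with 17 and 7 adjusted over the list alone. G1 regulators and oral tumour suppressors were higher in 18 and lower in 9 of 33 (0.442), with 18 and 10. In that list the stem cell factor SOX2 was 84.8-fold higher, the chloride channel ANO1 at least 46-fold higher and the imprinted cyclin kinase inhibitor CDKN1C at least 112-fold lower. CDKN2A, which encodes p16 and ARF, fell by 2.67 (SE 0.16), and cyclin D1, CCND1, differed by 0.04 (SE 0.16, adjusted p = 0.847). Targets of p53 were higher in 9 and lower in 9 of 26 (0.932), also adjusted over the list alone.

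The remaining lists did not pass in camera in the main setting either. With normexp on median signals, 5 lists gained a call, namely homeobox factors (0.0264), ribosomal proteins (0.0136), basal keratinocyte genes (0.0264), immediate-early and heat-shock genes (0.0304) and fibroblast and pericyte markers (0.00999). In the main setting these 5 had adjusted p from 0.587 to 0.978 with an estimated correlation. Homeobox and developmental factors were higher in 30 and lower in 17 of 57 members (camera adjusted p = 0.137), with 31 and 17 adjusted over the list alone. HOXD10 was at least 109-fold higher, and IRX4 fell by 7.83 (SE 0.24), being above background on 3 of the 4 OSC-19 arrays. Cancer-testis antigens were higher in 5 and lower in 5 of 13 (0.898), with 6 and 5 adjusted over the list alone. DDX43 was at least 51.3-fold higher and MAGEA6, whose probe may bind other MAGEA genes, 60.1-fold lower. NRF2 targets were higher in 14 and lower in 16 of 41 (0.969), with 15 and 16 adjusted over the list alone. Genes of oxidative phosphorylation were higher in 16 and lower in 12 of 55 (0.862), and housekeeping genes higher in 5 and lower in 3 of 15 (0.839), both with the same counts adjusted over the list alone. Cytosolic ribosomal proteins were higher in 4, lower in 7 and not passing in 64 of 75 (0.898), with 1 and 4 adjusted over the list alone. The direction of the median, the mean and the test differed for the mesenchymal, partial EMT, stress keratin, protease, p53, NRF2 and ribosomal lists. The Wnt ligand list had a mean of 0.000, beside a median of 0.156 and a test direction of higher on OSC-19 arrays.

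Markers of other cell types were mostly not above background. Of 16 fibroblast and pericyte markers 6 were tested, 4 of which other lists also held, and 4 were higher and 1 lower on OSC-19 arrays (camera adjusted p = 0.137), also adjusted over the list alone. They include CSPG4, a pericyte proteoglycan, at least 21.8-fold higher, beside ACTA2. Only 4 of 14 endothelial markers were tested, of which 2 were higher and 0 lower, also adjusted over the list alone. Leukocyte markers were higher in 1 and lower in 3 of 15 (0.839), and CD14, the endotoxin co-receptor, was 5.64-fold higher. Melanocyte, neural and muscle markers were higher in 0 and lower in 3 of 8 (0.228). The leukocyte and the melanocyte, neural and muscle lists kept those counts adjusted over the list alone.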

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

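The 3 tests on the conflict of labels and the test on the state of growth were chosen only after the result was seen, whereas those on random splits, brightness, probes of the same gene and the place of the spot were chosen before.

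The deposited value table and the scanner files assign the arrays to opposite lines. If the table merely had its signs turned, a column with the sign turned would follow its own scanner file closely, but the highest such r was 0.614. An exchange of the columns or of the files between the lines asks for a close match with the other line's file of the same number, and the lowest such r was 0.9999, which is consistent with an exchange. Whether the table or the scanner files hold the exchange stays open, as 0 scanner files name a line in their text. The size and the adjusted p of each difference do not depend on the answer, whereas every direction does.

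A split of the arrays at random was weighed for the comparison of the lines. Of the 35 exact splits of 8 arrays into 4 and 4, only 1, the real one, gave as many genes at least 2-fold different (4178, against 359 for the next, the split by slide). Likewise 1 of 35 gave as many genes past the threshold (8388, against 1637). Any other split leaves the difference between the lines in the spread within its sides, so few genes can pass. The low counts of genes in the other splits were thus largely set in advance and do not measure chance. For gene lists, 8 of 35 splits gave 9 or more, up to 14, so the number of lists past the threshold did not stand out. Among the 8 splits that part every replicate pair, the highest other count was 13. Splits with unequal shares of the lines still carry part of the difference between them. Among splits with equal shares, that of HSC-4 replicates 1 and 2 with OSC-19 replicates 3 and 4 gave 10 lists. The others gave at most 6. The split with 10 crosses line with slide, so it holds slide differences that differ between the lines. More than 9 lists were thus reached without a difference between the lines. For the lists, the splits therefore cannot tell whether chance would give as many.

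Arrays also differed between the slides in both lines. With line as a term, 8763 named genes differed in limma, 544 being at least 2-fold higher and 172 at least 2-fold lower on slide 2, and the slide held 10.2% of the sum of squares. The slide differences of the lines correlated at r = 0.701. A trend with brightness would account for little, as 91.6% of the slide sum of squares stayed after it was removed, which argues against it. The place of the spot held 0.71% of the variance. The processed signal had already been detrended across the surface, so this argues only against a broad effect of place left after that. If the slides had differed through the transcripts, probes of the same gene would shift together, and their r was 0.230, against 0.797 for the difference between the lines over 3569 genes, so hybridization or washing stays open.

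Cultures in another state of growth were weighed through the cell cycle, metabolism and stress lists, of which 2 shifted the same way in both lines at the preset correlation and 0 with an estimated one. The G1/S list shifted by -1.17 in HSC-4 and -0.45 in OSC-19, and oxidative phosphorylation by -0.40 and -0.32, so a difference in growth may contribute but is not established. Ribosomal proteins (-0.21 and -0.49) and antigen processing (0.21 and 0.21) also shifted alike in both lines, so the shift is not confined to lists of growth. Slide, scan and any difference in culture coincide and cannot be separated in these arrays. Among genes chosen after their values were seen, the ribosomal RNA gene RNA18SN5 was higher on slide 2 by 3.02 and the protease gene CTSZ differed by -2.71.

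The slide difference itself differed between the lines for 1453 named genes, for 371 of them by at least 2-fold. For IFI44L it was 0.39 in HSC-4 and 2.13 in OSC-19, larger by 1.74 in OSC-19, and CCL2 (1.42), FN1 (1.07), WNT5A (1.55) and WNT5B (1.49) also had a larger value in OSC-19. E2F2 had a slide difference of -2.16 in HSC-4 but -0.37 in OSC-19, which gave 1.80. Lower values in OSC-19 than in HSC-4 were found for MMP1 (-1.04), SERPINB3 (-1.79), PHLDA1 (-1.39), ATF3 (-1.24), LOX (-1.54) and DDX43 (-1.18). On HSC-4 arrays CCL2, SERPINB3 and DDX43 were not above background on any array, so their values there compare background signals and carry no weight. FN1, LOX and WNT5B were above background on 3 of the 4 OSC-19 arrays. At the preset correlation 14 lists had such an interaction, and 0 with an estimated one.

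Single arrays stood apart in 4 of 176 groups of 4 arrays (2.27%), drawn from the text genes and measures of array quality, by the Dixon test at n = 4, against 8.8 expected of independent arrays. The arrays of a line lie in pairs on the slides, which can hold this test down, so the low count is no evidence of quality. VSNL1 measured 1.20 on OSC-19 replicate 1, against 1.29 to 1.31 on the others, and SNAI2 -1.22 on the same array, against -1.41 to -1.38. PEG10 measured -8.24 there, against -7.44 to -7.32, all below background. NT5E measured 2.78 on HSC-4 replicate 4, against 2.61 to 2.62.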

How the results depend on the processing

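The filing of the arrays sets every direction, and the counts of genes past the threshold fell furthest with the normexp correction and with the averaging of arrays of a slide. The normexp correction, the averaging and the deposited table with columns exchanged were added after the results were seen. Of 83 text genes, 76 kept their call under every alternative that measured them, other than the deposited table as labelled, and 7 did not. With only probes above background on all 8 arrays, 50 of the 83 were measured. Under leave-one-out 4011 to 4205 genes were higher and 3667 to 3837 lower, and 9 to 10 lists passed. The planned use of mean spot signals was not used here.

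With normexp on the median signal, 2814 genes were higher and 2402 lower, 14 lists passed, the spread between replicates was 0.368 against 0.248, and the median of all genes was 0.184. With arrays of 1 line on 1 slide averaged, 2152 were higher and 1795 lower, with a spread of 0.265. By treat with a minimum log2 difference of 1, 1308 genes were higher and 1021 lower. Camera with an estimated correlation passed 0 lists and fry 26, and fry gave the opposite direction for matrix proteases (0.000896) and NRF2 targets (3.09e-05). The spread was 0.235 with quantile normalization, 0.260 with the median set to 0, 0.316 without a filter, 0.235 with only probes above background on all 8 arrays, 0.131 with slide as a block, 0.083 within slide 1, 0.101 within slide 2 and 0.136 with the replicate block.

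Single calls were lost for DLC1 with normexp (-1.64, adjusted p = 0.0873 in limma), SNAI2 with normexp (-0.25, 0.358) and EGFR with the mean of its probes (-0.39, 0.0594). With the arrays averaged they were lost, at unchanged differences, for E2F2 (0.0898), CDH1 (0.0769), VIM (0.0515) and SNAI2 (0.224). At the preset correlation, the G1/S list passed only with slide as a block (0.0378), the replicate block (0.0415), slide 2 alone (4.32e-05) or without HSC-4 replicate 1 (0.0164) or 2 (0.0257), and adjusted p = 0.908 with an estimated correlation and slide as a block.

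In the deposited table as labelled, all 9 lists passed in the opposite direction, with camera adjusted p of 5.45e-08 for interferon-stimulated genes, 0.0133 for cornified envelope, 0.0133 for EGF family, 0.0133 for antigen processing, 0.0133 for hypoxia, 0.00455 for inflammatory cytokines, 0.00178 for cholesterol synthesis, 0.0131 for the amino acid response and 0.00612 for YAP/TAZ targets.

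The same table gave these log2 differences for the largest genes: KRT6A -9.66, GSTM3 -9.73, MMP1 -9.12, CKMT1A -9.04, DUSP23 -8.47, CXCL1 -8.25, TNNT3 -7.67, IFI44L -6.91, KRT19P2 10.23, KRT19 9.88, IGFBP3 8.21, HCLS1 7.76, KLK5 7.74, GABRP 7.73, PADI3 7.68, MAGEB2 7.63. Interferon, antigen and inflammatory genes had IFI44 -5.03, PSMB9 -3.02, ERAP2 -2.90, B2M -1.78, CD14 -2.50. Growth factor, YAP/TAZ and metabolic genes had EPGN 3.97, PHLDA1 3.60, EGFR 0.91, NT5E 2.44, EGLN3 3.85, MSMO1 4.68, STARD4 2.98, LSS 2.08, VLDLR 3.89, ATF3 2.94, CHAC1 2.50, DUSP1 3.23. Keratins, adhesion and matrix genes had KRT5 -3.52, KRT15 -2.60, TP63 -0.99, CDH1 -0.80, VIM -1.27, SNAI2 0.44, CD44 2.13, PDPN 1.25, FN1 5.39, ACTA2 -4.94, LOX 4.41. Signalling, cell cycle and developmental genes had HES5 -4.59, NOTCH3 -3.08, WNT5B 4.80, SOX2 -6.41, CDKN2A 2.67, IRX4 7.84, MAGEA6 5.91, E2F2 -2.11. Genes not above background on any array of 1 line had nominal values, which compare with background signal and support only the bounds of the fold: CYB5A -10.53, S100A8 -8.99, FHOD3 -9.44, SERPINB3 -9.03, VSNL1 -7.94, SLFN11 -8.16, PXDN 11.54, PEG10 10.45, SGCE 10.07, CUZD1 9.78, IGFBP1 9.32, GDA 8.74, EPSTI1 -6.18, CCL2 -7.49, NRG4 -4.26, SLC2A3 6.77, CA9 -5.75, DLC1 5.83, MMP12 -7.30, MMP13 -7.22, WNT11 -4.70, CDKN1C 7.59, ANO1 -6.30, HOXD10 -7.75, DDX43 -7.78, CSPG4 -6.73. The values of KRT6C -8.95 and LCN2 7.61, above background on 1 and 2 arrays of the dim line, are likewise nominal.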

Other observations

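The settings with 2 or 10 neighbours and with families counted once were fixed in advance, but their use as tests of an explanation was chosen only after the result was seen.

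Genes that lie next to each other on a chromosome differed alike between the lines. Some of the stretches held known clusters, such as the serpins of chromosome 18 and the matrix proteases of chromosome 11. Others also held genes named almost alike, such as SLFN11, SLFN12 and SLFN13 on chromosome 17 and DUOX1 and DUOX2 on chromosome 15. For the rest no cluster is named here, apart from the keratins of chromosome 12. Whole chromosomes also leaned in 1 direction. No DNA was measured in these arrays.

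The difference of a gene correlated with the mean of its 5 neighbours on each side at r = 0.248 over 14191 genes. In 10000 permutations of gene order the highest value was 0.043, so that the permutation p was 1e-04, the smallest that number can give. Among 13663 windows of 25 genes, which overlap, 45 had a mean above 1.59 and 37 a mean below -1.27, limits that the most extreme window passed in 5% of permutations.

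The window ends named here were chosen after their values were seen. In windows and by chromosome, a gene counted as higher when its difference was positive, whether or not it passed the threshold. On chromosome 18, the window from RNF152 to CYB5A, which holds the SERPINB cluster, had a mean of 2.16, with 22 of 25 genes higher on OSC-19 arrays (adjusted permutation p = 3e-04). On chromosome 11, the window from PIWIL4 to MMP13 had a mean of 1.94, with 18 higher (adjusted permutation p = 0.0019). Its MMP10, MMP12 and MMP13 (6.95, 7.30 and 7.22) were not above background on any HSC-4 array. The same holds for CYB5A and SERPINB3 in the window of chromosome 18. Such nominal values enter the window means, and no window was run without these genes. On chromosome 12, the window from GALNT6 to KRT78, which runs into the type II keratin cluster, had a mean of 1.77, with 18 higher (adjusted permutation p = 0.0083). Further higher windows ran from CATSPER2 to COXFA4L3 on chromosome 15 (mean 1.80, 21 higher, adjusted permutation p = 0.0069), from CPE to WWC2-AS2 on chromosome 4 (1.73, 24 higher, 0.0134) and from TMEM98 to CCL15 on chromosome 17 (1.67, 21 higher, 0.0221). The smallest p among these windows was that of a lower one, from CD59 to SEC14L1P1 on chromosome 11, which holds CD44, with a mean of -1.80 and 1 of 25 genes higher (adjusted permutation p = 2e-04). Other lower windows ran from METTL21A to SMARCAL1 on chromosome 2 (-1.52, 3 higher, 0.0034), from PISD to IFT27 on chromosome 22 (-1.39, 2 higher, 0.0137), from TPTE to CCT8 on chromosome 21 (-1.37, 2 higher, 0.0177) and from HBP1 to CAPZA2 on chromosome 7 (-1.30, 0 higher, 0.0369).

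By chromosome, 9 passed the threshold in camera at the preset correlation and 1 with an estimated one. Chromosome 22 was lower on OSC-19 arrays, with a median of -0.69 and 22.9% of 371 genes higher (camera adjusted p = 2.03e-07, and adjusted p = 0.00043 with an estimated correlation). Chromosome 15 had a median of 0.69 with 79.9% of 482 genes higher (camera adjusted p = 1.39e-08), and adjusted p = 0.0634 with an estimated correlation. Chromosome 21 had a median of -0.43 with 22.6% of 168 genes higher (camera adjusted p = 8.85e-06), and adjusted p = 0.0958 with an estimated correlation. A window need not follow its chromosome. Chromosome 7, with a lower window, had a median of 0.39 with 69.1% of 709 genes higher (camera adjusted p = 0.00118, and 0.0958 with an estimated correlation). Chromosome 4, with a higher window, had a median of -0.20 (camera adjusted p = 0.13).

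If gene families made the neighbours alike, r would fall with families counted once, and it fell by 5.12%, to 0.235. A family was read from the opening characters of the symbol, so related genes such as KRT5 and KRT6A counted as different families. Copies named almost alike thus account for little of r, whereas other related genes stay open. Shared probes were not tested. A difference in copy number would reach beyond the nearest genes, and 98.4% of r at 2 neighbours was kept at 10. Each r takes the mean of the neighbours, which grows steadier with more genes. The share kept therefore does not measure how far the likeness reaches. It cannot tell a difference in copy number from shared control of long regions, so the cause stays open.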
